A study of Mus musculus with 9 samples.

How the data were processed

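RNA from the medial prefrontal cortex of mice was sequenced in 9 libraries of 3 groups, with 3 libraries per group. The groups are an unstressed control, a model of chronic unpredictable stress (CUS), and a running model, which the labels list as exercise. According to the series description, running was studied in mice exposed to the stress. The labels also carry the terms 4 week and week 8, with no statement of what each period refers to. Replicates were numbered 1 to 3 within a group by order of listing, so equal numbers do not pair libraries. The labels do not state that each library came from a separate animal, and p-values therefore measure the spread between these libraries, which may be partly technical.

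Per the labels' protocols, total RNA was extracted with Trizol, polyadenylated RNA was selected on oligo(dT) beads, and random-primed cDNA was made into circularised single-strand libraries. Nothing in the protocol marks the strand, so reads of a gene and of an antisense partner cannot be told apart. Per the submitters' processing notes, the tools were Bowtie2 2.2.5, RSEM 1.2.12 and DESeq2 1.4.5, and the genome build was mm10. The role of each tool and the annotation release are not given in the sources used here. The authors deposited FPKM values, that is, fragments per kilobase of transcript scaled to the mapped fragments of the library, rounded to 2 decimals. The read depth behind these values is unknown, so no counting interval or detection floor could be given, and a value of exactly 0 is described only as listed at 0. The deposited table had 65389 rows. The 16127 circular RNA rows, 2959 microRNA rows and 11178 rows with a numbered identifier from the sequencing provider were at 0 in all 9 libraries, which left 35125 rows with a gene identifier of NCBI.

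Values were analysed as log2(FPKM + 0.5) without further scaling. Genes with at least 0.5 FPKM in at least 3 of the 9 libraries were kept, which gave 14013 genes. Fold changes refer to the log2(FPKM + 0.5) scale and understate the change of low genes. Each of the 3 comparisons (CUS against control, running against CUS, running against control) was tested with limma 3.58.1 in R 4.3.3, with 1 model of all 9 libraries, moderated variances with an intensity trend, and Benjamini-Hochberg adjustment over the 14013 genes. A gene was called at an adjusted p under 0.05. The model had 6 residual degrees of freedom and a median of 4.71 prior degrees of freedom. For a single gene, an exact test of 3 libraries against 3 cannot give a p under 0.1, so the gene tests rest on the variance shared across genes.

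Before the data were examined, 34 gene lists were fixed for neuronal activity, stress hormone response, synapses, cell types of the cortex, neighbouring tissues, metabolism and signalling. The 32 lists with at least 5 kept genes were tested with camera of limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. The same lists were tested with camera at an estimated correlation, and with fry, which asks whether the genes of a list move on balance in one direction. The list of sex-linked genes had 4 kept genes, and that of mitochondrially encoded genes had 0, so neither was tested. Some lists share members, for example 3 genes between the inhibitory neuron and stress peptide lists and 2 between the glucocorticoid and inflammatory lists. The median log2 change of a list is given with the number of members above and below 0. The count of members called over all genes is given beside the count adjusted over the list alone. A list score per library is the mean over members of the log2 value minus the mean of that gene over the 9 libraries.

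Genes were named by a rule fixed before the data were examined. Where fewer than 10 genes were called in a comparison, the rule takes the 10 higher and 10 lower genes with the smallest unadjusted p, with a mean of at least 1 FPKM and no overlap between the 3 values of each group. These genes are stated as not passing the adjusted threshold unless said otherwise. Predicted genes, genes named as Riken clones and Y-linked genes were passed over. For each list, up to 4 members called over the list alone were named in a comparison, smallest p first, and for lists with no such member up to 2 members with the highest mean. Some genes that the rule takes are not reported here. Coordinates are those of GRCm38.p6, the assembly behind mm10, from the RefSeq gene table matched on the gene identifier, and 13984 of the 14013 kept genes had a match.

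The correlation between the CUS minus control and running minus CUS changes was set beside 100 simulations of 3 unchanged groups, because the CUS libraries enter both changes with opposite sign. The same code was tested on simulated data made from the means and spreads of the 14013 genes, with 200 genes changed. For running against CUS it called 95.5% of the genes changed by 2-fold, 88.1% of those changed by 1.5-fold and 20.9% of those changed by 1.25-fold. For CUS against control these shares were 100%, 85.1% and 23.9%, and for running against control 95.5%, 76.1% and 29.9%. Unchanged genes gave 5, 8 and 10 calls in CUS against control, running against CUS and running against control. The simulated genes varied independently, which the genes of a real library do not. Changing 200 genes also eases the adjusted threshold, so these shares do not bound how many genes changed in the data. For example, Fos differed by 2.69-fold between running and CUS and was not called (limma adjusted p = 0.0776).

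The alternatives fixed before the data were examined were a rescaling to TPM, median-of-ratios size factors, quantile normalization, pseudocounts of 0.1 and 1, no expression filter, a filter of 1 FPKM in 3 libraries, variance moderation without the trend or with a robust prior, models of only the 2 groups compared, library quality weights, each library left out in turn, and thresholds of adjusted p under 0.1 and unadjusted p under 0.01. Removal of a trend with transcript length and GC content in each library was added after the data were seen. It used the longest GENCODE M21 transcript of each gene, found for 98.7% of the kept genes, and a local regression fitted without the ribosomal protein and oxidative phosphorylation lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.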

Results

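Gene expression was measured as FPKM in the medial prefrontal cortex of control mice, of mice of the CUS model and of mice of the running model, with 3 libraries in each group. The questions were how chronic unpredictable stress changes the transcriptome of this cortical area, and what running does to it in stressed mice. Each library held between 17071 and 17280 genes above 0 FPKM, and FPKM values summed to between 370441 and 423257 per library. The highest sum belonged to CUS replicate 3, while the other 8 libraries lay between 370441 and 393663. Across genes, the log2 values of CUS replicate 3 had a mean Pearson r of 0.987 with the other libraries, and those of the other 8 libraries had means between 0.990 and 0.993. The first principal component held 30.3% of the variance, with CUS replicate 3 at 28.4 and the other libraries between -10.8 and 8.09. Xist was listed at 0 in each of the 9 libraries, and Ddx3y, a Y-linked gene, lay between 9.37 and 11.2 FPKM.

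In CUS mice compared with controls, genes of the neuronal activity response, the immediate early genes, were lower, and so were genes induced by glucocorticoids and genes of myelin, while genes of cytosolic ribosomes and of oxidative phosphorylation were higher. These shifts passed the list test with a preset correlation, and with an estimated correlation 0 lists were called (adjusted p between 0.419 and 0.613 for these 5). At the level of single genes 1 of 14013 was called. That gene was Gm36327 (chromosome 6, 47675582 to 47678797), a predicted protein-coding gene that falls outside the naming rule and was chosen after its values were seen. It had 0.79, 0.89 and 0.90 FPKM in the controls and was listed at 0 in each CUS and running library (limma adjusted p = 0.00300). No fold change is given against a value of 0. A listed 0 can be a failed estimate, and whether it is one here cannot be settled from FPKM values. The count of called genes was 2 without control replicate 1 or CUS replicate 2, and 6 without control replicate 2.

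Among the genes with the smallest p values that did not pass, the higher ones in CUS were Tmem40, Pigx, Hes5, Lsm10, Serinc2, Fam43b, Prpsap1, Foxo6, Phf23 and Tiam2. Tmem40 (chromosome 6, 115729131 to 115762466) had 3.69 ± 0.281 FPKM in CUS and 1.97 ± 0.206 in controls (SD, n = 3 each), a log2 difference of 0.77 (SE 0.107, limma adjusted p = 0.106). Hes5, a transcriptional repressor downstream of Notch, had 12.9 ± 1.80 against 7.71 ± 1.18 FPKM, a log2 difference of 0.71 (limma adjusted p = 0.224). The lower ones were Pde7b, Ninl, Hif3a, Sp2, Dpy19l4, Klhdc7a, Ier2, Clic4, H1f2 and Kirrel2. Pde7b, a phosphodiesterase that degrades cyclic AMP, had 4.04 ± 0.335 FPKM in CUS and 6.64 ± 0.0451 in controls, a log2 difference of -0.66 (SE 0.106). H1f2, a linker histone, had 3.75 ± 0.580 against 7.27 ± 1.54 FPKM. At an unadjusted p under 0.05 there were 2058 genes, 1247 higher and 811 lower in CUS. Independent genes would give 700.65 by chance, and the highest other split of the same 6 libraries gave 1606. The values of the groups did not overlap for 19.7% of genes, where chance gives 10%.

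**Figure D1:**
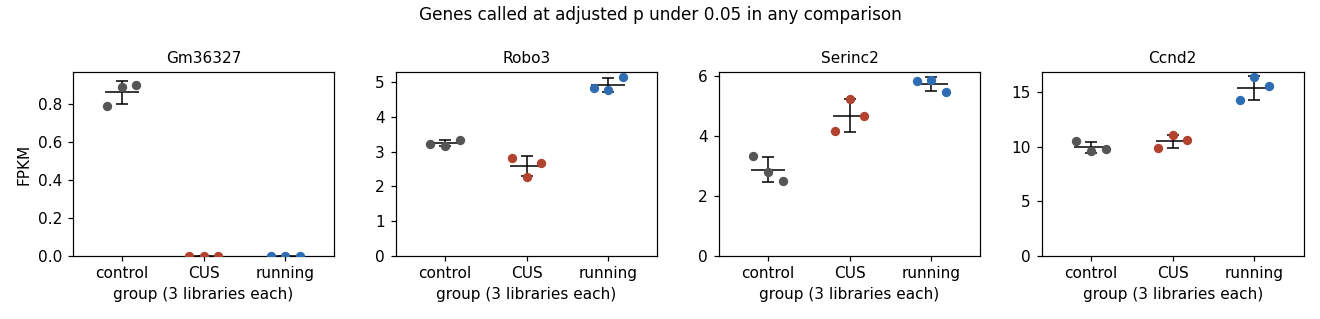
FPKM of the 4 genes called at an adjusted p under 0.05 in at least 1 comparison, for the control, CUS and running groups (x axis), with FPKM from 0 on the y axis. Points are libraries, and the horizontal line and bar are the mean and SD of 3 libraries. Gm36327 is listed at 0 in the 6 CUS and running libraries, and Robo3 lies between 4.79 and 5.15 in running against 2.26 to 2.81 in CUS.

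Of 31 measured immediate early genes, 26 were lower and 5 higher in CUS than in controls, with a median log2 change of -0.51 (camera adjusted p = 9.41e-14, adjusted p = 0.419 with an estimated correlation). The call over all genes held 0 members, and 21 members were lower when adjusted over the list alone. Fos, a component of the AP-1 transcription factor, had 8.67 ± 2.77 FPKM in CUS and 19.6 ± 6.49 in controls, a log2 difference of -1.12 (SE 0.254). Ier2 had a log2 difference of -0.91, Dusp1, a phosphatase of MAP kinases, one of -0.79, and Nr4a1, an orphan nuclear receptor, one of -0.64. Control replicate 2 had an immediate early gene score of -0.22, against 0.29 and 0.27 in the other controls, and the CUS scores lay between -0.46 and -0.32. Of 24 glucocorticoid-induced genes, 22 were lower, with a median of -0.33 (camera adjusted p = 6.13e-11, adjusted p = 0.419 with an estimated correlation), 0 over all genes and 9 adjusted over the list alone. Hif3a had 2.06 ± 0.499 FPKM against 3.77 ± 0.440, a log2 difference of -0.75. Plin4, which coats lipid droplets, had a log2 difference of -1.24, Galnt15 one of -0.61 and Zbtb16 one of -0.41. Without control replicate 3 the median of the glucocorticoid list was -0.22 (adjusted p = 1.59e-07).

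Each of the 76 genes of oxidative phosphorylation was higher in CUS, with a median of 0.21 (camera adjusted p = 8.56e-15), and so was each of the 82 cytosolic ribosomal protein genes, with a median of 0.22 (camera adjusted p = 2.90e-14). Both had an adjusted p = 0.613 with an estimated correlation, and 0 members of either list were called over all genes or adjusted over the list alone. Both scores were highest in CUS replicate 3, at 0.47 for ribosomal proteins and 0.36 for oxidative phosphorylation, and CUS replicates 1 and 2 lay between 0.01 and 0.13. Without CUS replicate 3 the medians were 0.09 for ribosomal proteins and 0.11 for oxidative phosphorylation. With the trend of transcript length and GC content removed, an alternative chosen after seeing the data, they were 0.10 and 0.08 (adjusted p = 2.28e-08 and 1.58e-07).

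Of 27 genes of mature oligodendrocytes and myelin, 26 were lower in CUS, with a median of -0.40 (camera adjusted p = 1.20e-11, adjusted p = 0.523 with an estimated correlation). The call over all genes held 0 members, and 2 were lower when adjusted over the list alone. These were Myrf, the transcription factor that drives myelin genes, with a log2 difference of -0.66, and Mobp, a myelin protein, with 21.3 ± 4.89 FPKM against 39.6 ± 15.0, a log2 difference of -0.84. Control replicate 3 had a myelin score of 0.66, the other controls -0.01 and 0.13, and without it the median was -0.20 (adjusted p = 2.07e-06) and the differences of Myrf and Mobp were -0.43 and -0.55. With library quality weights that of Mobp was -0.55. The same library had 212 FPKM of Ttr, a transcript abundant in choroid plexus, against at most 38.8 in the other 8.

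Smaller shifts passed the preset test in 11 further lists, with camera adjusted p between 4.12e-04 and 0.0346. With an estimated correlation their adjusted p lay between 0.419 and 0.618. The lower lists were the glutamatergic synapse (27 of 30 members lower, median -0.08), oligodendrocyte precursors (13 of 16, median -0.18), neurotrophic factors (13 of 16, median -0.15), mural cells (12 of 13, median -0.20), astrocytes (17 of 22, median -0.07), presynaptic vesicle machinery (16 of 23, median -0.08), endothelium (16 of 22, median -0.16) and striatal projection neurons (12 of 20, median -0.03). The higher lists were microglia (21 of 24 members higher, median 0.11), interferon response (21 of 24, median 0.13) and antioxidant genes (16 of 20, median 0.10). Over all genes 0 of their members were called, and adjusted over the list alone Rims1, an active zone scaffold, was lower (log2 -0.26) and P2ry12, a microglial purinergic receptor, was higher (log2 0.35). Without CUS replicate 3 the calls for microglia, endothelium, antioxidant genes and striatal neurons were lost, with adjusted p of 0.184, 0.168, 0.188 and 0.0630. The astrocyte call was lost without control replicate 3 (adjusted p = 0.0999). The striatal list was lost without control replicate 2, where its median was 0.02 (adjusted p = 0.656), and the antioxidant list without control replicate 1 or 2 (adjusted p = 0.0602 and 0.0603). The interferon list was lost without control replicate 2 or 3 (adjusted p = 0.0826 and 0.0540) and without CUS replicate 1 or 2 (adjusted p = 0.0831 and 0.257). Other medians also moved by over 1.5 times without 1 library. Without control replicate 3 they were -0.06 for oligodendrocyte precursors, -0.03 for astrocytes, -0.30 for mural cells and -0.09 for striatal neurons. Without control replicate 1 they were -0.12 for astrocytes and -0.05 for striatal neurons, and without control replicate 2 the neurotrophic median was -0.10. Without CUS replicate 1 the mural median was -0.31 and the striatal one -0.05, and without CUS replicate 2 the microglial median was 0.19 and the endothelial one -0.25. Without CUS replicate 3 the medians were -0.04 for the presynaptic list, -0.13 for astrocytes, 0.07 for microglia and -0.04 for endothelium. With the length and GC trend removed, the glutamatergic, antioxidant, interferon, microglial and striatal calls were lost, at medians of -0.05, 0.06, 0.06, 0.08 and -0.04.

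The 16 lists that did not pass in CUS against control were excitatory and inhibitory neuron markers, GABA-A receptor subunits, monoamine genes, stress peptides and steroid receptors, meninges, choroid plexus, olfactory regions, thalamus and hypothalamus, blood cells, inflammatory cytokines, the circadian clock, heat shock, the Wnt pathway, insulin signalling and lipid synthesis. Their camera adjusted p lay between 0.118 and 0.913 and their medians between -0.14 and 0.24. Over all genes 0 of their members were called. Adjusted over the list alone, 4 were, of which Per2 of the clock was higher (log2 0.40), Wnt7a was higher (log2 0.45), Ptgs2, an inducible prostaglandin synthase, was lower (log2 -0.41) and Atf5 was lower (log2 -0.31). The abundant neuronal transcripts Camk2a and Slc17a7 averaged 918 and 726 FPKM over the 9 libraries, Npy 192 and Sst 535. Median, mean and test differed in sign for excitatory neurons, stress peptides, olfactory regions, the clock and lipid synthesis.

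In running mice compared with CUS mice, immediate early genes were higher and the genes of ribosomes and oxidative phosphorylation were lower. With an estimated correlation these lists had adjusted p of 0.354, 0.502 and 0.502 and were not called. One gene was called, Robo3 (chromosome 9, 37416045 to 37433436), a receptor that guides axons across the midline. It had 4.93 ± 0.195 FPKM in running, 2.58 ± 0.286 in CUS and 3.25 ± 0.0929 in controls (SD, n = 3 each), a log2 difference from CUS of 0.82 (SE 0.0870, limma adjusted p = 0.0227). There were 928 genes at an adjusted p under 0.1, of which 297 were higher and 631 lower. At an unadjusted p under 0.05 there were 3287 genes, where independent genes would give 700.65 and the highest other split of the 6 libraries gave 2169, and 24.9% of genes had no overlap between groups, where chance gives 10%. Without CUS replicate 2 the count called was 1518 genes, 458 higher and 1060 lower, and without any of 7 other libraries, control replicates 1 and 3 among them, it was 0. Without control replicate 2 it was 21.

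The higher genes with the smallest p values after Robo3 were Ccnd2, Setd7, Egr4, Nr4a1, Dusp5, Fos, Anxa11, Egr2 and Ccnd1, with limma adjusted p between 0.0657 and 0.0776. Fos had 23.4 ± 1.49 FPKM in running against 8.67 ± 2.77 in CUS, a log2 difference of 1.43 (SE 0.254), and Egr2, a zinc finger transcription factor, had 7.91 ± 1.75 against 2.12 ± 0.371, a log2 difference of 1.67 (SE 0.299). The D-type cyclins Ccnd2 and Ccnd1 had log2 differences of 0.53 and 0.47. The lower genes were Grp, Eif4ebp1, Ccdc12, Nppc, Surf1, Cd68, Cnpy2, Mrpl46, Plp2 and Ninj1, with adjusted p between 0.0574 and 0.0776. Grp, a neuropeptide precursor, had 14.4 ± 2.10 FPKM against 26.2 ± 3.08, a log2 difference of -0.84 (SE 0.106). Eif4ebp1, a repressor of cap-dependent translation, had 5.23 ± 0.508 against 9.40 ± 1.38, a log2 difference of -0.78, and Nppc, the precursor of C-type natriuretic peptide, had 4.69 ± 0.315 against 7.45 ± 0.996. Of these 10 lower genes, 8, all but Grp and Eif4ebp1, moved by over 1.5 times toward 0 with the length and GC trend removed, to log2 differences between -0.37 and -0.14.

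Of the 31 immediate early genes, 30 were higher in running than in CUS, with a median of 0.71 (camera adjusted p = 1.01e-20, adjusted p = 0.354 with an estimated correlation). The call over all genes held 0 members, and 25 were higher and 1 lower when adjusted over the list alone. Without CUS replicate 2, where 1518 of 14013 genes were called, the call over all genes held 15 members. Leaving out CUS replicate 3 instead gave 0 called genes. Nr4a1 had 71.2 ± 4.31 FPKM against 38.3 ± 1.43, Egr4 had 32.4 ± 1.93 against 18.8 ± 1.97, and Dusp5 had 6.34 ± 0.684 against 3.32 ± 0.379. The running scores lay between 0.21 and 0.35. Of 24 glucocorticoid-induced genes, 21 were higher, with a median of 0.28 (camera adjusted p = 6.18e-08, adjusted p = 0.441 with an estimated correlation), 0 over all genes and 7 adjusted over the list alone. Sgk1, a serum and glucocorticoid kinase, had 29.4 ± 1.92 FPKM against 20.2 ± 0.262, and Klf9, Errfi1 and Ddit4 had log2 differences of 0.30, 0.28 and 0.51.

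**Figure D2:**
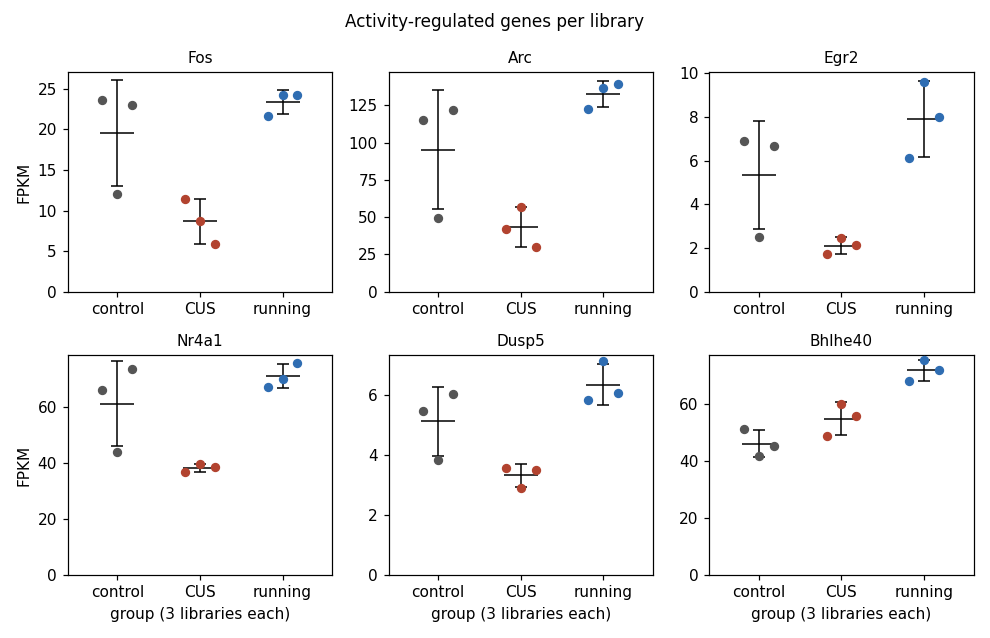
FPKM of 5 immediate early genes (Fos, Arc, Egr2, Nr4a1, Dusp5) and of the clock gene Bhlhe40 per library (y axis, from 0) in the control, CUS and running groups (x axis). Points are libraries, and the horizontal line and bar are the mean and SD of 3 libraries. Arc lies between 30.3 and 57.0 in CUS and between 123 and 139 in running, while control replicate 2, at 49.3, lies among the CUS libraries. Arc was chosen for display after its values were seen.

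Each of the 82 ribosomal protein genes was lower in running than in CUS, with a median of -0.36 (camera adjusted p = 1.01e-22), as was each of the 76 oxidative phosphorylation genes, with a median of -0.30 (camera adjusted p = 2.97e-20). Both had an adjusted p = 0.502 with an estimated correlation. Over all genes 0 members were called, and adjusted over the list alone 79 and 66 were lower. Without CUS replicate 2, where 1518 of 14013 genes were called, the call over all genes held 50 and 49 members. Leaving out CUS replicate 3 instead gave 0 called genes, so these counts rest on which library is left out. Rps19 had 171 ± 10.1 FPKM in running, 246 ± 47.4 in CUS and 196 ± 12.5 in controls. The log2 differences between running and CUS were -0.50 for Rpl39 and -0.35 for Rpl10. Among respiratory chain genes, Ndufs7 of complex I had 87.6 ± 4.83 FPKM against 113 ± 6.10, and Atp5j2, Ndufs5 and Ndufa8 had log2 differences of -0.41, -0.34 and -0.26. CUS replicate 3 had the highest scores of both lists, and without it the medians were -0.22 for ribosomal proteins and -0.19 for oxidative phosphorylation. With the length and GC trend removed they were -0.15 and -0.09 (adjusted p = 4.38e-17 and 5.62e-08). The log2 differences were then -0.20 for Rpl39, -0.10 for Rpl10, -0.14 for Ndufs7, -0.05 for Ndufs5 and -0.01 for Ndufa8. With quantile normalization they were -0.34 for Rps19, -0.18 for Rpl10, -0.25 for Atp5j2 and -0.16 for Ndufa8, and after rescaling to TPM Ndufa8 had -0.16.

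**Figure D3:**
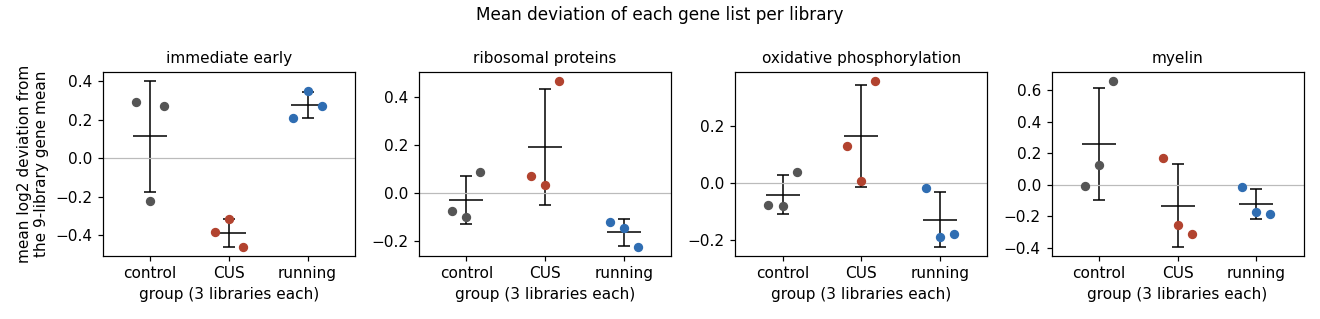
Mean log2 deviation of 4 gene lists from the mean of each gene over 9 libraries (y axis), per library in the control, CUS and running groups (x axis). Points are libraries, and the horizontal line and bar are the mean and SD of 3 libraries. The CUS immediate early scores lie between -0.46 and -0.32, CUS replicate 3 has the highest ribosomal score at 0.47, and control replicate 3 has the highest myelin score at 0.66.

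The other 6 lists that passed the preset test in running against CUS had smaller medians and camera adjusted p between 2.04e-04 and 0.00954. With an estimated correlation their adjusted p lay between 0.354 and 0.641, and 0 of their members were called over all genes. Without CUS replicate 2, where 1518 of 14013 genes were called, these were 8 microglial, 6 glutamatergic, 4 presynaptic, 4 insulin, 3 clock and 0 neurotrophic genes. Leaving out CUS replicate 3 instead gave 0 called genes. Microglial genes were lower (21 of 24 members, median -0.22), and the glutamatergic synapse (25 of 30 higher, median 0.06), the circadian clock (15 of 19, median 0.07), insulin, PI3K and mTOR signalling (19 of 26, median 0.08), presynaptic vesicle machinery (17 of 23, median 0.06) and neurotrophic factors (13 of 16, median 0.13) were higher. Without CUS replicate 3 the microglial median was -0.11, and without running replicate 1 that call was lost (adjusted p = 0.0694). The clock median was 0.04 without CUS replicate 3 and 0.11 without running replicate 1, and the presynaptic median was 0.10 without running replicate 2 and 0.01 without running replicate 3. With the length and GC trend removed the microglial median was -0.06 (adjusted p = 0.0452), and the insulin, glutamatergic and neurotrophic calls were lost, at medians of 0.01, 0.05 and 0.10. Up to 16 lists were called when the 6 libraries were split in ways that mix the groups. Adjusted over the list alone, the microglial genes Cd68, P2ry13 and Gpr34 were lower (log2 -0.41, -0.32 and -0.42). The synaptic genes Grin2a, Grin2b, Shank2 and Dlgap2 were higher, with log2 differences between 0.29 and 0.46, and so were Cplx2 and Rims1 of the presynapse (0.30 and 0.28). In the clock list Per1 (0.71), Bhlhe40 (0.39) and Tsc22d3 (0.50) were higher and Dbp was lower (-0.29), and in the insulin list Irs2, an insulin receptor substrate, was higher (0.59) and Eif4ebp1 lower. The clock list shares 1 gene with the immediate early list and 1 with the glucocorticoid list, so these lists are not fully separate. With the length and GC trend removed the log2 differences were -0.20 for Cd68, -0.27 for Gpr34, 0.13 for Grin2a, 0.24 for Grin2b, 0.23 for Shank2 and -0.16 for Dbp. After rescaling to TPM Dbp had -0.19, and without CUS replicate 3 Gpr34 had -0.27. Vgf and Ntrk2, of the neurotrophic list, averaged 181 and 94.6 FPKM over the 9 libraries.

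The 22 lists that did not pass in running against CUS were excitatory and inhibitory neuron markers, GABA-A receptor subunits, monoamine genes, stress peptides, myelin, oligodendrocyte precursors, astrocytes, endothelium, mural cells, meninges, choroid plexus, striatal neurons, olfactory regions, thalamus and hypothalamus, blood cells, inflammatory cytokines, interferon response, heat shock, antioxidant genes, the Wnt pathway and lipid synthesis. Their camera adjusted p lay between 0.0617 and 0.959 and their medians between -0.28 and 0.32. Myelin had a median of 0.03. Meningeal genes were lower for 19 of 22 members (median -0.28, camera adjusted p = 0.0680, adjusted p = 0.820 with an estimated correlation). That list passed the preset test in 6 of 11 alternatives and in 3 of 9 models with 1 library left out, namely without control replicate 3, CUS replicate 2 or running replicate 2. Median, mean and test differed in sign for 8 of them, namely excitatory neurons, stress peptides, mural cells, striatal neurons, thalamus, heat shock, the Wnt pathway and lipid synthesis. Over all genes 0 members of these lists were called. Without CUS replicate 2, where 1518 of 14013 genes were called, these were 5 antioxidant genes and at most 2 genes in any other of these lists. Leaving out CUS replicate 3 instead gave 0 called genes. Adjusted over the list alone, the serotonin receptor gene Htr2a was higher (log2 1.01, SE 0.183), with 9.29 ± 2.40 FPKM in running and 4.31 ± 0.847 in CUS. Among interneuron genes Cort, Tac1 and Sst were lower (-0.35, -0.35 and -0.34) and Gad2 was higher (0.19). Tac1 was also called in the striatal list. Tnr and Gpr17 of the oligodendrocyte precursor list were higher (0.43 and 0.44), Egfl7 of endothelium was lower (-0.31), Ramp3 of the thalamic list was lower (-0.60) and Ptgs2 was higher (0.47). Mgst1, Txn1, Sod1 and Gsta4, which detoxify oxidants, were among 7 lower antioxidant genes, with log2 differences between -0.52 and -0.27, and Fdps of sterol synthesis was lower (-0.36). With the length and GC trend removed the log2 differences were -0.07 for Cort and for Sst, -0.21 for Tac1, 0.28 for Tnr, -0.18 for Egfl7, -0.30 for Mgst1, -0.12 for Txn1 and -0.09 for Gsta4. Quantile normalization gave -0.15 for Sst and -0.09 for Sod1, and TPM gave -0.17 for Sod1 and 0.29 for Gad2. Gsta4 had -0.21 without CUS replicate 3 and -0.19 with quality weights. Aldoc and Glul of astrocytes averaged 298 and 599 FPKM over the 9 libraries, Ptgds and Mgp of meninges 759 and 31.2, Enpp2 and Ttr of choroid plexus 60.1 and 42.1, and B2m and H2-D1 of the interferon list 104 and 18.9.

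In running mice compared with controls, 3 genes were called. By the series description the running mice were also stressed, so this comparison does not separate running from stress. Serinc2 (chromosome 4, 130253495 to 130279218), a serine incorporator of membranes, rose from 2.87 ± 0.424 FPKM in controls to 5.72 ± 0.223 in running, with 4.67 ± 0.540 in CUS (SD, n = 3 each), a log2 change of 0.89 (SE 0.107, limma adjusted p = 0.0265). Ccnd2 (chromosome 6, 127125162 to 127152188), cyclin D2, rose from 9.96 ± 0.495 to 15.4 ± 1.09 FPKM, with 10.5 ± 0.609 in CUS, a log2 change of 0.60 (SE 0.0730, limma adjusted p = 0.0265). The predicted gene Gm36327 was again listed at 0 (adjusted p = 0.00300). At an adjusted p under 0.1 there were 33 genes, 20 higher and 13 lower, and at an unadjusted p under 0.05 there were 1628, where independent genes would give 700.65 and the highest other split gave 537. The share of genes with no overlap between groups was 22.4%, where chance gives 10%.

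Each of Serinc2 and Ccnd2 lost its call when control replicate 2 or 3 or any running library was left out, with adjusted p up to 0.201, and the count was then 1 gene. It was 7 without control replicate 1 or CUS replicate 2, and 10 without CUS replicate 1 or 3.

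The higher genes that did not pass were Kcng1, Bhlhe40, Per2, Sbk1, Fastkd5, Nuak1, Zswim4 and Robo3, with limma adjusted p between 0.0586 and 0.0684. Bhlhe40, a repressor of clock genes, had 71.7 ± 3.62 FPKM against 46.0 ± 4.75, a log2 difference of 0.64 (SE 0.0905), and Per2, a core clock component, had 13.4 ± 1.10 against 8.66 ± 0.901, a log2 difference of 0.61 (SE 0.0862). The lower genes were Nppc, Lor, Mas1, Acbd4, Ninl, Eif4ebp1, Ramp3, Slc25a34, Fam71e1 and Prrt4, with adjusted p between 0.0684 and 0.101. Nppc had a log2 difference of -0.62, and Ramp3, a receptor activity-modifying protein, one of -0.64.

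Each of the 27 myelin genes was lower in running than in controls, with a median of -0.36 (camera adjusted p = 3.28e-09). With an estimated correlation the 9 lists called in this comparison with the preset one had adjusted p between 0.929 and 0.998. Without control replicate 3, the library with the highest myelin score, the median was -0.15 (adjusted p = 8.12e-05). Immediate early genes were higher for 22 of 31 members, with a median of 0.23 (camera adjusted p = 1.26e-04), and this call was lost without control replicate 2, where the median was 0.09 (adjusted p = 0.349). Ribosomal protein genes were lower for 80 of 82 members (median -0.14, camera adjusted p = 1.37e-06) and oxidative phosphorylation genes for 73 of 76 (median -0.09, camera adjusted p = 6.30e-04). The latter call was lost without control replicate 3 or running replicate 2 (medians -0.05 and -0.06, adjusted p = 0.0872 and 0.191), and without running replicate 1 the median was -0.15. Without control replicate 3 the ribosomal median was -0.08. After removal of the length and GC trend it was -0.05 (adjusted p = 7.53e-04), and the oxidative phosphorylation and insulin calls were lost, at medians of -0.01 and 0.04. Endothelial genes were lower for 22 of 22 members (median -0.16, camera adjusted p = 3.04e-04) and mural cell genes for 12 of 13 (median -0.26, camera adjusted p = 0.00144). Both calls were lost without running replicate 1 (medians -0.10 and -0.17, adjusted p = 0.0768 and 0.102), and without running replicate 2 the endothelial median was -0.30. That library had an endothelial score of 0.20, above the 3 controls at 0.07 to 0.15, and the other running libraries had -0.23 and -0.20. The meningeal scores of running replicates 1, 2 and 3 were -0.49, 0.35 and -0.35. The clock was higher for 14 of 19 members (median 0.10, camera adjusted p = 3.53e-04), with a median of 0.04 without running replicate 2. Blood cell genes were higher for 5 of 9 (median 0.66, camera adjusted p = 0.00161) and insulin, PI3K and mTOR signalling for 15 of 26 (median 0.06, camera adjusted p = 0.0259). The blood score of control replicate 3 was 0.45, above running replicates 1, 2 and 3 at 0.01, 0.25 and 0.10. The other controls had -0.19 and -0.65. Without control replicate 2 the blood median was 0.47 (camera adjusted p = 0.0329), and over 20 alternatives its lowest value was 0.04. The insulin call was lost without control replicate 3 or running replicate 3 (adjusted p = 0.0872 and 0.202). Splits of the 6 libraries that mix the groups called up to 16 lists.

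Over all genes 0 members of these lists were called. Adjusted over the list alone, Per2, Bhlhe40, Cry2 and Nr1d2 were among 5 higher clock genes, with log2 differences of 0.61, 0.64, 0.18 and 0.16. Alas2, the erythroid enzyme of haem synthesis, and the haemoglobin genes Hbb-bt, Hbb-bs and Hba-a1 were among 5 higher blood genes, with log2 differences of 0.93, 0.67, 0.83 and 0.72. Hbb-bs had 345 ± 19.6 FPKM in running, 266 ± 42.1 in CUS and 200 ± 60.3 in controls. Ier5 and Nr4a3 were the 2 higher immediate early genes (0.37 and 0.71), and Irs2 and Deptor were higher in the insulin list (0.62 and 0.29), with Eif4ebp1 lower (-0.61). Egfl7 of endothelium and Myl9 of mural cells were lower (-0.31 and -0.39).

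The 23 lists that did not pass in running against control were glucocorticoid-induced genes, neurotrophic factors, the glutamatergic synapse, presynaptic machinery, excitatory and inhibitory neuron markers, GABA-A receptor subunits, monoamine genes, stress peptides, oligodendrocyte precursors, astrocytes, microglia, meninges, choroid plexus, striatal neurons, olfactory regions, thalamus and hypothalamus, inflammatory cytokines, interferon response, heat shock, antioxidant genes, the Wnt pathway and lipid synthesis. Their camera adjusted p lay between 0.215 and 0.998 and their medians between -0.18 and 0.07. Median, mean and test differed in sign for 7 of them, namely presynaptic machinery, stress peptides, olfactory regions, thalamus, inflammatory cytokines, interferon response and the Wnt pathway. Over all genes 0 members of these lists were called. Adjusted over the list alone, Errfi1 and Bcl6 of the glucocorticoid list were higher (0.29 and 0.26) and Hif3a and the metallothionein Mt2 lower (-0.47 and -0.56). Serpina3n, an acute phase protein, was higher (0.33), and Cort (-0.31), Cd68 (-0.29), Syndig1l (-0.72), Dcx (-0.41) and Ramp3 (-0.64) were lower. Cort had -0.18 with the length and GC trend removed.

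The last comparison asked whether running moved genes against the direction of the CUS effect. Across 14013 genes, which are not independent replicates, the CUS minus control and running minus CUS changes had a Pearson r of -0.59. The CUS libraries enter both changes, and 100 simulations of 3 unchanged groups gave a mean r of -0.50, between -0.55 and -0.44. Those simulations gave all groups the same spread, while the mean variance was 0.0350 in CUS, 0.0269 in control and 0.0227 in running. A larger spread in CUS makes the chance r more negative, so the observed r cannot be read as a reversal beyond chance. The covariance was -0.0214, and the simulated mean was -0.00738, between -0.00868 and -0.00625, a difference of -0.0140. The spread used there was below that of each group, a comparison added after the data were seen. Divided by the 3 libraries, the mean variance was 0.00897 in control, 0.0117 in CUS and 0.00755 in running. The simulated covariances thus lie too close to 0, and the CUS spread, the one shared here, gives a chance covariance of -0.0117. Without CUS replicate 2 the observed covariance was -0.0370, for which no chance value from the remaining CUS libraries is given. Without CUS replicate 3 the observed r was -0.50 and the covariance -0.0147, and the spread of the 2 remaining CUS libraries gives -0.0113. Of the 200 genes with the smallest p in CUS against control, 90.5% had the opposite sign in running against CUS, where unchanged groups gave a mean of 91.3%. Of the same 200 genes, 82% lay on the same side of control in running as in CUS, where unchanged groups sharing the controls gave a mean of 91.6%, between 85.5% and 96%. Across all genes the CUS minus control and running minus control changes had an r of 0.40, where unchanged groups gave 0.50 (0.45 to 0.56). Their covariance was 0.0129, where unchanged groups gave 0.00733 (0.00630 to 0.00893) and the spread of the controls alone gives 0.00897. With 3 libraries per group, a split into parts of at least 2 libraries was not possible, so part of either excess covariance may come from the shared libraries.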

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

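The removal of the length and GC trend was chosen after seeing the data, and the other alternatives before. Where a count changed, the cause was not tested unless stated. For CUS against control 1 gene was called, and the count was 0 with the filter of 1 FPKM, which removes Gm36327, 8 with library quality weights, 520 at an unadjusted p under 0.01, and between 1 and 6 with 1 library left out, highest without control replicate 2. For running against CUS 1 gene was called, and the count was 0 with no filter and 0 after the length and GC trend was removed. It was 2 with size factors, with quantile normalization and with the robust prior, 15 with only the 2 groups, 2178 with quality weights (689 higher, 1489 lower), 928 at an adjusted p under 0.1 and 1243 at an unadjusted p under 0.01. With 1 library left out it lay between 0 and 1518, highest without CUS replicate 2. The quality weights were lowest for CUS replicates 3 and 2, at 0.244 and 0.575. They were highest for CUS replicate 1, at 2.61, so the weighted CUS values rest largely on that library. For running against control 3 genes were called, and the count was 1 with no filter, where more genes were tested, 7 without the trend, 24 with only the 2 groups, 147 with quality weights, 10 after the length and GC trend was removed, 33 at an adjusted p under 0.1, 493 at an unadjusted p under 0.01, and between 1 and 10 with 1 library left out.

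For gene lists, 16, 10 and 9 were called in CUS against control, running against CUS and running against control. With an estimated correlation 0, 0 and 0 were called, with 2, 3 and 1 at an unadjusted p under 0.05, and with fry 0, 0 and 0, with 5, 8 and 1. The fry p depends on the order of the groups in the design, and another order gave 0, 0 and 0 with 5, 9 and 1. With 1 library left out the counts lay between 13 and 17, 10 and 14, and 7 and 10. Of the lists called, immediate early genes in CUS against control and in running against CUS, glucocorticoid-induced genes, ribosomal proteins and myelin kept their direction and call in each alternative of camera with the preset correlation, though the ribosomal median moved from 0.22, -0.36 and -0.14 in the 3 comparisons to 0.10, -0.15 and -0.05 with the length and GC trend removed. The myelin median in CUS against control was -0.40, and -0.15 in the alternative that brought it nearest 0. After the length and GC trend was removed, oxidative phosphorylation had a median of -0.01 in running against control (adjusted p = 0.772), and insulin signalling had adjusted p of 0.734 and 0.375 in running against CUS and against control. That removal also ended the glutamatergic call in CUS and running against CUS (adjusted p = 0.0979 and 0.0797), the neurotrophic call in running against CUS (0.0689), and in CUS the antioxidant, interferon, microglial and striatal calls (0.127, 0.307, 0.0886 and 0.0886). The median moved little for the glutamatergic list in running against CUS, from 0.06 to 0.05, and grew in size for the striatal list, from -0.03 to -0.04. Quality weights ended the antioxidant, endothelial and mural calls in CUS (0.0655, 0.0702 and 0.0539, at medians of 0.08, -0.07 and -0.10), quantile normalization the antioxidant call in CUS and the insulin call in running against control (0.0917 and 0.0777), and the filter of 1 FPKM the interferon call (0.0957). Alternatives also called lists that had not passed, foremost meninges and blood cells in running against CUS, in 6 and 3 of 11 alternatives and in 3 and 5 of 9 models with 1 library left out. The robust prior was not run for lists, since camera offers none. No gene named for its change and no called list changed the direction of its test, though the striatal median in CUS turned to 0.02 without control replicate 2. Sizes held less well, since of 60 genes named for their change in running against CUS, 27 moved by over 1.5 times toward 0 with the length and GC trend removed, and 7 with quantile normalization. Of the genes called, Robo3 lost its call with no filter, after the trend was removed (adjusted p = 0.0599) and in 7 of 9 models with 1 library left out. In all 9 its limma adjusted p lay between 0.0161 and 0.143, and in those 7 between 0.0505 and 0.143. Over 21 alternatives its log2 difference lay between 0.73 and 0.99. The rule also named 16 genes by level alone, whose log2 changes had the other sign in 76 of 1008 values and in 28 of 48 gene and comparison pairs. After that was seen they were treated as mean levels with no direction, and these stayed within 1 SD in 176 of 176 values. Most of these values are means with 1 of the 9 libraries left out. Such a mean cannot move by 1 SD of the same libraries, so the count shows little. No scaling moved the median of all genes by over 0.1. Rescaling to TPM moved it most, from -0.03 to 0.06 in running against CUS and from 0.02 to -0.04 in CUS against control. Moves of that size match the smaller list medians. The reversal correlation lay between -0.71 and -0.50 with 1 library left out, and in the other alternatives it stayed within its jackknife spread of 0.184. Read depth is unknown, so no limit from counting error can be given.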

Other observations

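Of 12 families of genes defined by symbol after the data were seen, 7 passed the preset test both in CUS against control and in running against CUS. With an estimated correlation their adjusted p lay between 0.314 and 0.422 in these comparisons, and none was called. Each of 78 mitochondrial ribosomal protein genes was higher in CUS than in control, with a median of 0.17, and each was lower in running than in CUS, with a median of -0.25 (camera adjusted p over 12 families = 8.28e-13 and 1.82e-15). Proteasome subunits had medians of 0.16 and -0.18 (6.54e-09 and 1.50e-07), Sm and Sm-like proteins of the spliceosome 0.17 and -0.25 (8.08e-05 and 3.93e-05), and vacuolar ATPase subunits 0.14 and -0.15 (0.00633 and 0.0144). Voltage-gated potassium channels went the other way, with medians of -0.11 and 0.18 (0.00127 and 5.20e-07), as did collagens with -0.12 and 0.06 (4.32e-04 and 0.00707) and clustered protocadherins with -0.06 and 0.06 (0.00339 and 0.0184). The CUS libraries enter both comparisons with opposite sign, so mirrored medians can arise with no effect. In running against control, the proteasome, Sm, vacuolar ATPase, collagen and protocadherin families had camera adjusted p between 0.729 and 0.842. No values with the length and GC trend removed or a library left out are given for these families, so that trend cannot be told apart here.

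Dual specificity phosphatases passed in running against CUS (median 0.04, adjusted p = 0.04999, adjusted p = 0.315 with an estimated correlation). In running against control the haemoglobin genes had a median of 0.67 (adjusted p = 0.00131, adjusted p = 0.386 with an estimated correlation). Potassium channels had 0.09 and mitochondrial ribosomal proteins -0.06 there (adjusted p = 0.00945 and 0.0213, adjusted p = 0.943 with an estimated correlation for both). Zinc finger proteins, core histones and solute carriers passed in 0 comparisons, with camera adjusted p between 0.0713 and 0.928.

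The criteria for single libraries, for the control range and for the removed trend were written only after the result was seen. Models with each library left out had been planned. The criteria for matched genes, member profiles and splits were written before, those for matched genes after the medians with the trend removed were known. Immediate early genes were lower in CUS and higher in running. The smallest median in running against CUS with 1 library left out was 0.60, and after the length and GC trend was removed the median was 0.71, which argues against a single library or that trend as the whole cause. What stays open is handling or activity before tissue collection, since the 3 control libraries themselves spread over 0.51 of the list score and the design does not separate collection from group. An effect of running or stress on activity-regulated transcription may equally account for the pattern and was not tested.

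Ribosomal and oxidative phosphorylation genes were higher in CUS than in control and lower in running than in CUS. For running against CUS, the scores of CUS replicates 1 and 2 in the 2 lists lay above the 3 running libraries in 4 of 4 cases. This argues against CUS replicate 3 as the only library above running. The cases are 2 libraries on 2 lists and not independent, and the narrowest was 0.01 against -0.02 for oxidative phosphorylation. Control replicate 3, at 0.09 and 0.04, lay above running as well. For CUS against control, CUS replicates 1 and 2 lay above the 3 controls in 1 of 4, so CUS replicate 3 cannot be told apart from the group there. With a trend of transcript length and GC content removed, both lists stayed past the preset threshold. Their medians were then -0.15 and -0.09 in running against CUS, from -0.36 and -0.30. In CUS against control they were 0.10 and 0.08, from 0.22 and 0.21. Passing decides little, since splits of the running and CUS libraries that mix the groups called up to 16 lists at that threshold. The longest transcript may also differ from the length behind the FPKM values, which would leave part of a trend in place. The trend may account for much of the shift, and whether it accounts for all of it is not decided. Matched genes do not decide it either. Those of the other lists, as written beforehand, gave -0.0925 in running against CUS but were longer and less abundant (1484 bases and 90.3 FPKM, against 1100 and 189). Those in no list, a departure that was seen first, gave -0.23 at 1212 bases and 137 FPKM. A difference between the groups stays open and was not tested apart from that trend.

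Mature oligodendrocyte genes were lower in CUS and running than in control. Without control replicate 3 the medians were -0.20 in CUS and -0.15 in running, from -0.40 and -0.36, so that library may account for much of the difference, while both calls held at the preset correlation (adjusted p = 2.07e-06 and 8.12e-05) and neither was called with all libraries at an estimated one (adjusted p = 0.523 and 0.998). CUS replicate 1, with a myelin score of 0.17, lay above the other 2 controls at -0.01 and 0.13. A different share of white matter in the dissection stays open, because across members the profile of control replicate 3 against the other controls correlated with that of CUS against the same controls at -0.560, past the -0.5 set beforehand, and with that of running at -0.0196, which did not reach it. In 1000 simulations of unchanged, independent genes, added after the result was seen, the shared controls alone gave means of 0.429 and 0.436, and 0 and 17 simulations were at or under the observed values. Genes of a real library vary together, so these counts do not measure chance for this list. A change in oligodendrocytes with stress was not tested.

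The 10 possible splits of the 6 libraries of a comparison are too few for a share under 0.05. For genes, the real split called 1, 1 and 3 in CUS against control, running against CUS and running against control, the highest other split called 0 in each, and 1 of 10 splits, the real one, gave as many. At an unadjusted p under 0.05 the real splits gave 2058, 3287 and 1628 genes and the highest others 1606, 2169 and 537. For gene lists, the real split called 16 in CUS against control and the highest other 15, with 1 of 10 giving as many. In running against CUS the real split called 10 lists and the highest other 16, and in running against control the numbers were 9 and 16, with 9 of 10 splits giving as many in both. In these 2 comparisons, splits that mix the groups thus called as many lists as the real one or more.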
